A study of Mus musculus with 2 samples.

How the data were processed

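The series holds 2 mouse liver samples, 1 fetal and 1 adult, prepared for reduced representation bisulfite sequencing (RRBS), an assay that reads methylation in the CpG-rich part of the genome cut out by a restriction enzyme. Per the labels' protocols, genomic DNA was digested with MspI, which cuts at CCGG, the ends were made blunt and given an A, adapters were ligated, and gel slices meant to hold digestion products of 40 to 120 bp and of 120 to 220 bp were treated with bisulfite and amplified by PCR. The submitters' processing notes name the mouse build mm9. The trimming tool, aligner and methylation caller are not given in the sources used here.

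Each of the 4 deposited files, 1 per library and read end, is a list of the reads in which the authors' processing found sequencing adapter, per the file headers. A line holds the read name, the read length, the first and last matched base in the read and in the adapter, the length of the match and its number of mismatches. These positions, lengths and mismatch numbers are the only measurements, and they are in bases and not normalized. Every listed read was 49 bases long, the adapter was 34 bases long, and listed matches covered 10 to 34 bases, as tested on the files. No line carries a methylation call, a read sequence or a genomic position. The methylation comparisons planned for this design, namely the global CpG level, differential CpG sites, promoter levels of 7 gene lists and bisulfite conversion, were therefore not analysed here, and no gene, locus or coordinate is reported. The analysis followed the rules that had been fixed for adapter lists before the data were examined, as had the other choices named below except where stated.

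The number of bases before the adapter in a read was taken as its insert length. When a read and its mate both showed the adapter from its first base at the same position, the pair was called a same-start pair, in which both reads measured 1 molecule of that length. A match that began inside the adapter occurred only in reads with an insert length of 0. Mates were joined by read name. Read 1 was the main data and read 2, matches without mismatches, matches of at least 10 bases and same-start pairs were the alternatives. For the length peaks, same-start pairs were added after the data were seen. Gaps could not be filtered on, because the lists have no column for them. The 5 length classes and the comparison of read 1 matches with and without a listed mate were chosen after the data were seen. A length peak was a length whose count reached at least 2 times the median of its 10 neighbours, 5 on each side. This could be asked of the 30 lengths from 5 to 34 bases, and at most the 5 highest peaks per library were to be named. Simulated counts were drawn with counting error alone around a smooth curve fitted to the read 1 counts of each library. A planted peak of 3 or 5 times its background was found in 100% of 200 simulations over these 30 lengths. Peaks of 1.5 times, below the limit of 2, were found in 0%, and 0 false peaks per simulation arose. Real counts can be more uneven than such a curve, so the absence of false peaks does not carry over to them.

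There was 1 library per stage, so no test between stages was possible and no p-value is given. The libraries were sequenced on different flow cells, in lane 2 for fetal and lane 6 for adult liver, so stage, library preparation and sequencing run are confounded. Shares carry 95% Wilson intervals and fetal to adult ratios the interval of the corresponding share. These cover counting error only. They treat each listed sequence as independent, which PCR copies of a molecule are not, so they can be too narrow even for that. The standard deviation over the 48 tiles imaged in each lane is given as a technical spread within a library. It says nothing about the spread between animals. The total number of reads per library was not used here, so the share of all reads that carried adapter is unknown. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used.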

Results

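The series compared liver DNA of fetal and adult mice by RRBS, within a study of circadian oscillators in the fetal liver and their entrainment by the mother's feeding. The data analysed were lists of reads matched to the sequencing adapter, which give the number of such matches and, for each, the number of bases before the adapter. The fetal library had 598597 listed read 1 sequences and 532296 listed read 2 sequences. The adult library had 129056 and 64274. Because a match had to cover at least 10 of the 49 bases, the listed inserts ran from 0 to 39 bases, all shorter than the lower bound of 40 bp intended for the gel slices. The levels of methylation at circadian genes or elsewhere were not analysed here.

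The first comparison asked how many adapter matches were listed for the fetal and adult livers. The fetal library had 4.64 times as many listed read 1 sequences as the adult library (95% interval 4.61 to 4.67), and 8.28 times as many listed read 2 sequences (8.21 to 8.35). Pairs listed at both ends numbered 529235 in fetal and 63870 in adult liver, a ratio of 8.29 (8.22 to 8.35). Of these pairs, 97.9% in fetal and 94.9% in adult liver were same-start pairs, 518336 and 60592 in all, and their ratio was 8.55 (8.48 to 8.63). The fetal read 1 lists held 12471 ± 2235 sequences per tile (SD over 48 tiles), and the adult lists held 2689 ± 306. No fetal tile, with a lowest value of 8312, was as low as the highest adult tile, with 3263. Tiles are parts of 1 sequencing lane, and the total number of reads was not used, so these ratios compare the lists of 2 libraries and not the stages.

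The difference between read 1 and read 2 came from sequences listed at read 1 alone, which were similar in number, though not in share of the list, in the 2 livers. The fetal library had 69362 such sequences and the adult library 65186, a ratio of 1.06 (1.05 to 1.08). In the adult list, 49.5% of read 1 sequences (49.2% to 49.8%) had a listed mate, against 88.4% (88.3% to 88.5%) in the fetal list. In both livers most of them were matches with 2 mismatches at insert lengths of 37 or 38 bases, 57684 sequences or 83.2% of the fetal and 59470 sequences or 91.2% of the adult ones. At 38 bases, matches with 2 mismatches were 39.7% of fetal and 83.8% of adult read 1 sequences of that length, and a mate was listed for 0.250% and 0.0643% of them. Exact matches at the same length had a listed mate in 99.3% of fetal and 98.9% of adult sequences. In read 2, matches with 2 mismatches were 0.504% of fetal and 1.55% of adult sequences at 38 bases. At 39 bases, exact matches were 96.6% of fetal and 81.3% of adult read 1 sequences. Matches with 1 mismatch were the remaining 3.38% and 18.7%. Thus 38 bases was the longest insert at which 2 mismatches were listed, an edge of the lists. Matches with 2 mismatches and no listed mate numbered 49067 in fetal and 52858 in adult liver at 38 bases. They fell to 8617 and 6612 at 37 bases and to 364 and 440 at 36 bases.

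**Figure D1:**
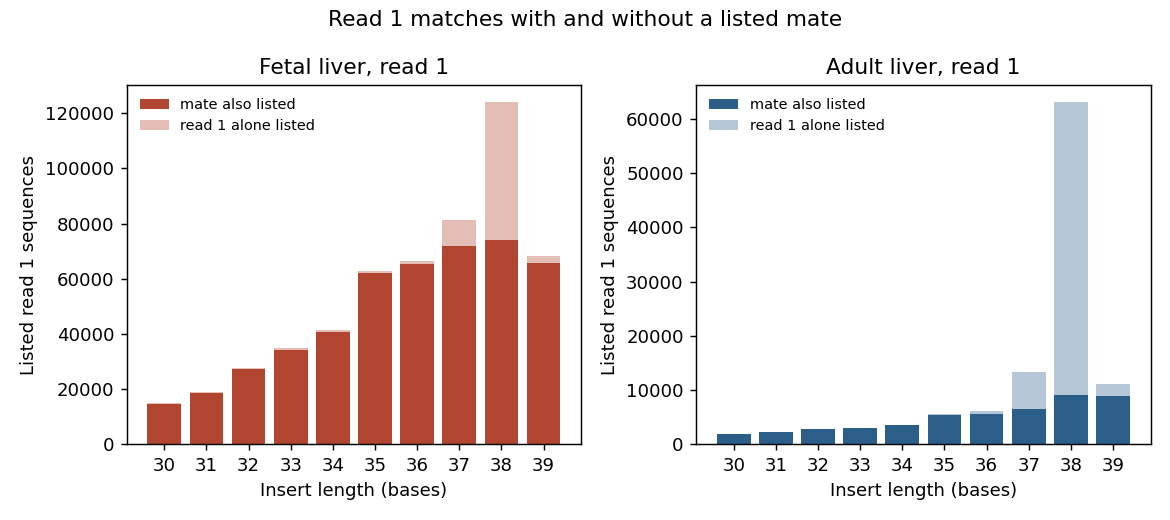
Listed read 1 sequences (vertical axis, number) by insert length from 30 to 39 bases (horizontal axis) in the fetal (left) and adult (right) library, on separate scales. Dark bars are sequences whose mate was also listed and pale bars those listed at read 1 alone, which reached 50151 in fetal and 54020 in adult liver at 38 bases.

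The second comparison asked whether the inserts listed for the fetal and adult livers had the same lengths. Among same-start pairs the adult liver held relatively more of the shortest inserts. Inserts of 1 to 19 bases were 0.785% of fetal pairs (0.762% to 0.810%) and 5.40% of adult pairs (5.22% to 5.58%). The values over tiles were 0.786% ± 0.0732 and 5.40% ± 0.574 (SD over 48 tiles). Inserts of 20 to 29 bases were 8.22% ± 0.268 of fetal and 13.6% ± 1.08 of adult pairs. In the 2 longer classes the fetal share was the higher, with 26.0% ± 0.396 against 22.0% ± 1.34 at 30 to 34 bases and 65.0% ± 0.491 against 58.8% ± 1.55 at 35 to 39 bases. Length by length, the fetal share was the higher only from 32 to 37 bases. The adult share was the higher at 30 bases (3.09% against 2.80%) and 31 bases (3.72% against 3.56%). It was so again at 38 bases (15.0% against 14.2%) and 39 bases (14.8% against 12.6%). The median insert was 36 bases in fetal and 35 bases in adult pairs. Single tiles had medians of 36 bases in fetal and of 35 to 36 bases in adult liver. Inserts of 0 bases were 0.0567% of fetal and 0.191% of adult same-start pairs.

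In the read 1 lists, the main data, the order of the libraries was the opposite at 20 to 29 and at 35 to 39 bases. Inserts of 20 to 29 bases were 7.35% of fetal (7.29% to 7.42%) and 6.58% of adult sequences (6.44% to 6.71%). At 30 to 34 bases the order was that of the pairs, with 23.0% and 10.5%. Inserts of 35 to 39 bases were 67.2% of fetal (67.1% to 67.4%) and 76.8% of adult sequences (76.6% to 77.0%), and the medians were 36 and 38 bases. Read 2 gave 9.10% and 16.5% at 20 to 29 bases, 64.0% and 55.8% at 35 to 39 bases, and medians of 36 and 35 bases. Read 1 sequences with 0 bases of insert were 1.73% of fetal and 3.45% of adult sequences, or 10347 and 4447. Most of them, 7007 fetal and 2958 adult, opened inside the adapter while read 2 showed an insert, so these shares do not count molecules without insert. The direction of the difference at 20 to 29 and at 35 to 39 bases depended on whether the sequences listed at read 1 alone were counted. So did the adult read 1 median of 38 bases, the longest insert at which 2 mismatches were listed.

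**Figure D2:**
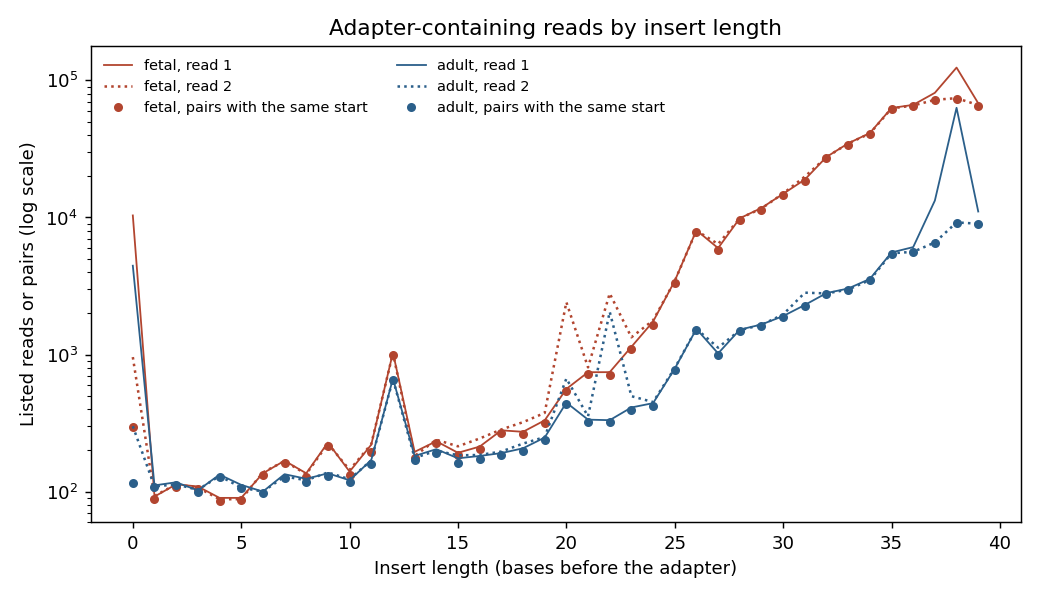
Number of listed sequences or pairs (vertical axis, log scale) by insert length in bases (horizontal axis) for the fetal and adult library, with solid lines for read 1, dotted lines for read 2 and points for same-start pairs. Adult read 1 rises to 63122 at 38 bases, where read 2 has 9201, and both libraries have a peak at 12 bases.

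Length by length, the fetal to adult ratio of same-start pairs was near 1 for inserts of 1 to 20 bases and above 10 from 33 to 37 bases. It was 1.24 (1.19 to 1.30) over inserts of 1 to 19 bases, with 4070 fetal and 3273 adult pairs. It was 1.25 (1.10 to 1.42) at 20 bases, 4.34 (4.01 to 4.69) at 25 bases and 7.76 (7.40 to 8.14) at 30 bases. Over 33 to 37 bases it was 11.4 (11.2 to 11.5). At 38 bases it was lower, at 8.07 (7.89 to 8.24), and at 39 bases it was 7.30 (7.14 to 7.46). Over the length classes the ratio was 5.15 (5.03 to 5.28) at 20 to 29 bases, 10.1 (9.92 to 10.3) at 30 to 34 bases and 9.46 (9.35 to 9.56) at 35 to 39 bases.

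**Figure D3:**
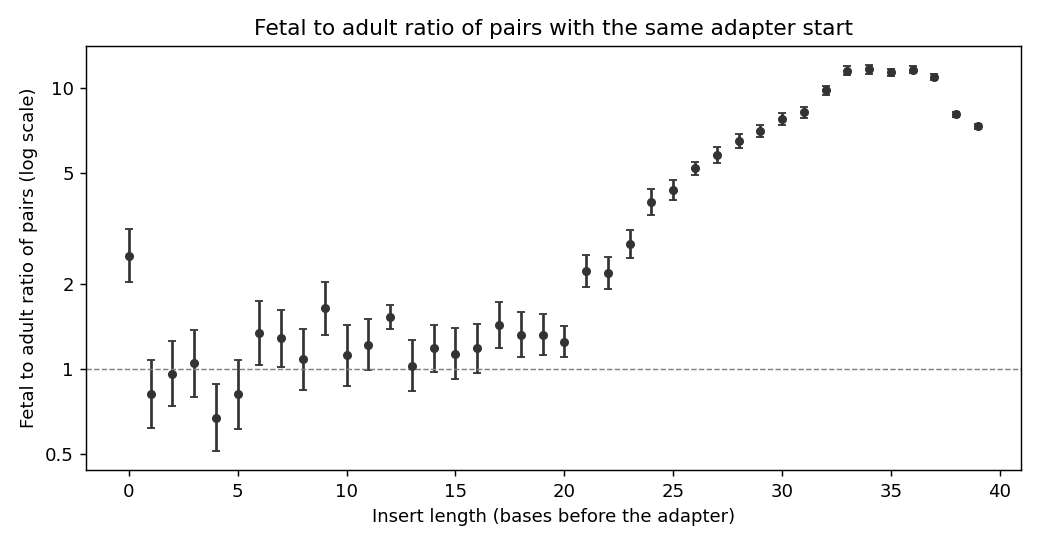
Fetal to adult ratio of same-start pairs (vertical axis, log scale) by insert length in bases (horizontal axis), with bars for the 95% interval of counting error and a dashed line at a ratio of 1. The ratio is 2.53 at 0 bases, lies between 0.672 and 1.65 from 1 to 20 bases, is 11.6 at 34 and at 36 bases and 7.30 at 39 bases.

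The third comparison asked whether single insert lengths stood out and whether they were the same in both livers. In read 1, 1 length passed in each library, and it was the same one, 12 bases. The fetal library had 1033 read 1 sequences of 12 bases, 5.06 times the median of the neighbouring lengths, and the adult library had 668, or 3.87 times. Same-start pairs of 12 bases numbered 997 in fetal and 650 in adult liver, and their fetal to adult ratio was 1.53 (1.39 to 1.69). Inserts of 26 bases stood 1.71 times above their neighbours in fetal and 1.70 times in adult read 1, below the limit of 2. Read 2 added a peak at 20 bases in both libraries, of 2411 fetal and 668 adult sequences, and a peak at 22 bases in the adult library, of 2050 sequences. In the fetal library read 2 held 2791 sequences of 22 bases, 1.79 times the neighbouring median, which did not pass. Among same-start pairs neither length passed. At 20 bases there were 542 fetal pairs, 1.06 times the neighbouring median, and 433 adult pairs, 1.54 times. At 22 bases there were 710 fetal pairs, 0.780 times, and 323 adult pairs, 0.793 times. The lists give no sequence, so the genomic origin of the 12-base inserts was not analysed here. Lengths below 5 and above 34 bases could not be tested, because they lack 5 neighbours on 1 side.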

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

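The read names carry an 8-base index tag that no comparison used. In read 1, 8259 fetal sequences, or 1.38% (1.35% to 1.41%), had a tag that differed from the library's own at 3 or more bases, and so did 1010 adult sequences, or 0.783% (0.736% to 0.832%). They are listed because the tags lie outside the comparisons and the counts exceed the 3 that 0 observed would allow, a bar that any ordinary rate of index read errors would pass. The most frequent such tag made up 1860 fetal and 208 adult sequences. Among all read 1 sequences, 3876 fetal and 934 adult ones had the library's own tag with 1 base missing and an A added at the end. These were counted whatever the number of differing bases, and their overlap with the tags above was not counted. The source of the tags that differed from the library's own was not tested.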

How the results depend on the processing

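A number of reads or peaks was said to hold if it stayed within 1.5 times the read 1 value. Medians, shares, their differences and ratios had to stay within the counting interval of the read 1 value. Read numbers were thus judged more loosely than shares and ratios. Of the 14 results, the fetal median and the number of fetal listed reads, 520018 to 598597, held in every alternative run. The fetal to adult ratio of listed reads, 4.64 in read 1, moved but stayed above 1. Restricting read 1 to matches without mismatches left 60850 adult sequences and a fetal to adult ratio of 8.55, pairs listed at both ends left 63870 and a ratio of 8.29, and read 2, added after seeing the data, gave 64274 and 8.28. The length classes were chosen after seeing the data. The fetal minus adult difference in the share at 35 to 39 bases, -9.54 percentage points in read 1, reversed to 8.15 in read 2, 6.70 without mismatches and 6.20 in same-start pairs. That at 20 to 29 bases, 0.775 points in read 1, reversed to -7.43, -5.18 and -5.42. The same 3 settings gave shares at 35 to 39 bases of 64.0%, 64.9% and 65.0% in fetal and 55.8%, 58.2% and 58.8% in adult liver, an adult median of 35 bases in each, and shares without insert of 0.180%, 0.307% and 0.0567% in fetal and 0.467%, 1.49% and 0.191% in adult liver. These settings leave out the read 1 matches with 2 mismatches by construction or nearly so. Among read 1 sequences without insert, such matches were only 6.70% in fetal and 6.84% in adult liver. They therefore account for little of the change in the shares without insert. Keeping only the library's own index tag, also added later, moved the fetal share without insert to 1.60%. Read 2 gave 2 peaks in fetal liver, at 12 and 20 bases, and 3 in adult liver, at 12, 20 and 22 bases, with 2 in both. A limit of 1.5 times the neighbours gave other lengths, 12 and 26 bases in fetal and 12, 20 and 26 bases in adult liver, so again 2, 3 and 2 in both. The 12-base peak was found in both libraries under each setting run, same-start pairs, added after seeing the data, included. The minimum of 10 aligned bases removed 0 sequences and so tested nothing. No replicate could be left out, because each stage had 1 library, and the planned methylation alternatives were not run because the lists hold no methylation values. No paired analysis was possible because each stage had 1 library.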

Other observations

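In both livers the number of listed reads was larger on tiles numbered 8 than on tiles numbered 1 within a swath. For same-start pairs the mean per tile was 1.79 times larger in fetal and 1.52 times larger in adult liver, and for read 1 matches with 2 mismatches at 37 or 38 bases and no listed mate it was 1.34 and 1.25 times larger. Among pairs listed at both ends, read 1 gave an insert 1 base longer than read 2 in 0.573% of fetal (0.553% to 0.594%) and 0.128% of adult pairs (0.103% to 0.159%). The opposite offset, read 1 shorter by 1 base, had the opposite order, with 0.0215% (0.0179% to 0.0259%) and 0.0783% (0.0594% to 0.103%).

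The tests below were all chosen after the results were seen. The read 1 matches with 2 mismatches at 37 and 38 bases are a pattern that matters for the order of the libraries at 35 to 39 bases. Sequencing errors in a true adapter are argued against, because a mate was listed for at most 0.442% of these reads, the value in the fetal library, where it should be listed for most. Insert sequence that resembles the adapter and a fault of read 1 at its last bases both stay open. Read 2 held at most 1.20% as many matches with 2 mismatches at these lengths, but this belongs to the pattern itself and both explanations allow it, and the lists hold neither sequence nor base quality. No biological explanation was tested.

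The fetal to adult ratio of same-start pairs was higher for long than for short inserts. A difference in sequencing depth alone is argued against, because the ratio at 35 to 39 bases was 7.60 times that at 1 to 19 bases. Similar total read numbers of the libraries, as a hypothesis, stay open, with a ratio of 0.970 for read 1 matches with 2 mismatches and no mate and of 1.24 for inserts of 1 to 19 bases. A gel cut at a different length stays open too: 14 of the 17 steps between neighbouring lengths from 20 to 37 bases went up, but this range was picked from the trend and so does not test it. The developmental stage of the liver is open and untested, since each stage had 1 library on its own flow cell.

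Many read 2 sequences at 20 and 22 bases belonged to pairs whose read 1 opened inside the adapter. In fetal liver 2028 pairs had 6 adapter bases missing in read 1 and 22 bases of insert in read 2, and 1834 pairs had 8 missing and 20 bases of insert. The adult numbers were 1709 and 216. The adult read 2 peak at 20 bases held 668 sequences, and 433 same-start pairs had this length, so pairs that opened inside the adapter were the smaller part of it. The missing bases and the read 2 insert added up to 28 or 32 in 87.2% of 7007 such fetal pairs and in 95.4% of 2958 adult pairs. These sums were picked from the same pairs, so their share does not test an insert made of adapter sequence, which stays open in the absence of read sequences. No biological explanation was tested.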
